A study of Mus musculus with 6 samples.

How the data were processed

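PolyA RNA of purified mouse platelets was sequenced from pools of suspensions of 1 genotype, 3 pools from Nxf1 mutants and 3 from wild-type littermates, all in 1 lane per the labels. The authors deposited whole-number counts per gene with each gene's length, per the file headers. Per the submitters' processing notes, CASAVA 1.8.2, Subread and featureCounts were used with the mm10 build. Their roles, their settings, the treatment of reads that map to several places and the use of strand are not given in the sources used here. The library kit named in the labels does not mark strand. The deposited counts cover 9822 genes, all above 0.5 CPM in at least 3 libraries, as found from the values. Genes carry Entrez identifiers, of which 9636 were named from the RefSeq table of GRCm38.p6, the assembly of mm10, 2 from GENCODE and 184 stayed without a name. Coordinates come from that RefSeq table, and exon numbers and GC content were found for 9589 genes in GENCODE. The exon number of a gene is the largest of any of its annotated transcripts, so other transcripts of the gene can have fewer. Norad had no exon number or GC content and is absent from comparisons that use them.

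Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling and a robust quasi-likelihood fit with genotype as the only term, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. The filter filterByExpr removed 0 genes. The common dispersion gave a biological coefficient of variation of 14.2%, and 5.73% with the preparation day as a block. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled totals, and shares of counts use the deposited totals. Gene lists of at least 5 members were tested with camera on voom values (limma 3.58.1) at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Library measures and shares of counts were compared with a two-sided exact permutation test over 16 measures, which cannot go below p = 0.1. The wild-type libraries also belong to another series per the labels. How many animals a pool held is not given in the sources used here, so p-values measure the spread between pools. Those of the gene tests also share variance across genes.

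The comparison, lists, alternatives and rule for named genes were set before the data were examined. The rule took Nxf1. It then took the 12 largest rises and 12 largest falls among called genes with a mean CPM of at least 10, the same direction on all 3 days and no overlap between genotypes, leaving out clone or predicted names and pseudogenes. It then took, per list, up to 4 called members with the smallest p, and last the 5 most abundant genes. Some genes that the rule takes are not reported here. Alternatives were other scalings, DESeq2 1.42.0, limma-voom with and without quality weights, other low-count filters, abundant or erythroid genes left out, stricter thresholds, each library or day left out, other list tests and the day as a block. The stricter thresholds were run for counts of genes and not for named genes. A length and GC correction (loess, span 0.5) and a blocked fit without day 1 were added after the data were seen. Histone classes were taken from GENCODE names after a first run had placed H4bc24, an H2B gene by its GENCODE name, in the wrong class.

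The labels give each pool a preparation day, with 1 mutant and 1 wild-type pool per day, so the day pairs the libraries. Deviations from the group means correlated across genes at 0.431, 0.271 and 0.481 within days and at most at -0.0104 between days. No 2 libraries of a group agreed within sampling noise, since the mean chi-square per gene was at least 14.5.

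The fits were tested on counts simulated from the means, library sizes and dispersions of this comparison, with each gene drawn independently of the others. Of genes changed 1.2-fold, 1.5-fold, 2-fold and 4-fold, the genotype-only fit recovered 0%, 30%, 79.6% and 100% among 9800 genes tested, and 6.3% of its calls were false. The blocked fit recovered 22.4%, 70%, 90% and 100% among 9811 genes, with 6% false calls. No effect of the preparation day was simulated, while libraries of the data deviated together within days. The rates of both fits therefore leave out how each handles the day. At most 50 genes were changed per fold, far fewer than the 2166 called in the data. The adjustment was thus stricter in the simulation, and recovery in the data may be higher. Of 40 simulated data sets of 9822 genes with no change, 7 had at least 1 of 28 lists past the threshold of camera with a preset correlation.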

Results

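Platelets, the anucleate blood cells that megakaryocytes release, were compared between mice heterozygous for the C587R change in Nxf1 and wild-type littermates. Nxf1 encodes the main receptor that carries mRNA out of the nucleus, and the comparison asks which platelet transcripts differ when 1 copy of the gene carries the change. PolyA RNA was sequenced from 6 libraries, 3 per genotype, each a pool of platelet suspensions from males of the BALB/c background in which over 98% of flow cytometry events carried the platelet marker CD41. A mutant and a wild-type pool were prepared on each of 3 days. The deposited tables listed 9822 genes, with totals of 25189231 to 29421549 counts per library, and each library had a count for at least 9820 of them. The 5 most abundant transcripts were the mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1, Ctla2a, Nrgn and the ferritin gene Fth1, and none passed the edgeR test between genotypes with TMM scaling. Fth1 had a log2 fold change of -0.22 (adjusted p = 0.205 by edgeR) and passed with the preparation day as a block (0.00729) and by limma-voom with quality weights (0.043). Fth1 and mt-Rnr2 (-0.15, adjusted p = 0.454 by edgeR) both passed with library size alone (0.00289 and 0.0143), among genes with a mean CPM of at least 10 (0.000323 and 0.00507) and by DESeq2 with the block (7.17e-05 and 0.0476). They also passed without wild-type replicate 3 (adjusted p = 0.0183 and 0.0305 by edgeR) and without day 3 (0.00543 and 0.0157), and mt-Rnr1 passed among genes with a mean CPM of at least 10 (0.0213). Over the alternatives run for named genes the adjusted p ranged from 7.17e-05 to 0.614 for Fth1, from 0.00507 to 0.894 for mt-Rnr2 and from 0.0213 to 0.961 for mt-Rnr1.

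Nxf1 (Entrez 53319, protein-coding, chromosome 19, 8757103 to 8770910, mm10) did not differ detectably at this depth. Its level was 3.29 ± 0.894 CPM in mutant and 3.73 ± 1.05 CPM in wild-type platelets (SD, n = 3 each). The log2 fold change was -0.19 ± 0.22 (SE, adjusted p = 0.604, edgeR quasi-likelihood test), and it was 0.08 without wild-type replicate 3. A missense change need not alter the level of its transcript, so this value does not check the genotype labels.

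Of the 9822 genes, 1266 were higher and 900 lower in mutant platelets (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05). Among these, 107 rose and 278 fell by more than 2-fold. Mutant and wild-type libraries did not overlap for 2117 of the 2166 called genes, and for 36.3% of all genes, where chance gives 10%. The excess of higher over lower calls was smaller with upper-quartile factors (1178 and 1026), without the 10 most abundant genes (1060 and 1014) and with library size alone (956 and 909), and among genes with a mean CPM of at least 10 fewer were higher (725) than lower (756). With the preparation day as a block, 2164 genes were higher and 1765 lower by edgeR, and all 2166 were called in the same direction. The blocked edgeR p-value of Vmp1 was 2.18e-143, lower than 3 pairs of 1 gene alone could give. Blocked edgeR calls thus rest largely on a variance shared across genes, and less on each gene's own spread. DESeq2 with the same block called fewer, 1582 higher and 912 lower, and 1907 of the 2166 were among them. Fewer genes passed without mutant replicate 2 (1382, of them 654 higher), without day 1 (1197, of them 610 lower) and without day 2 (1005, of them 485 higher and 520 lower), and 706 were higher without mutant replicate 1.

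**Figure D1:**
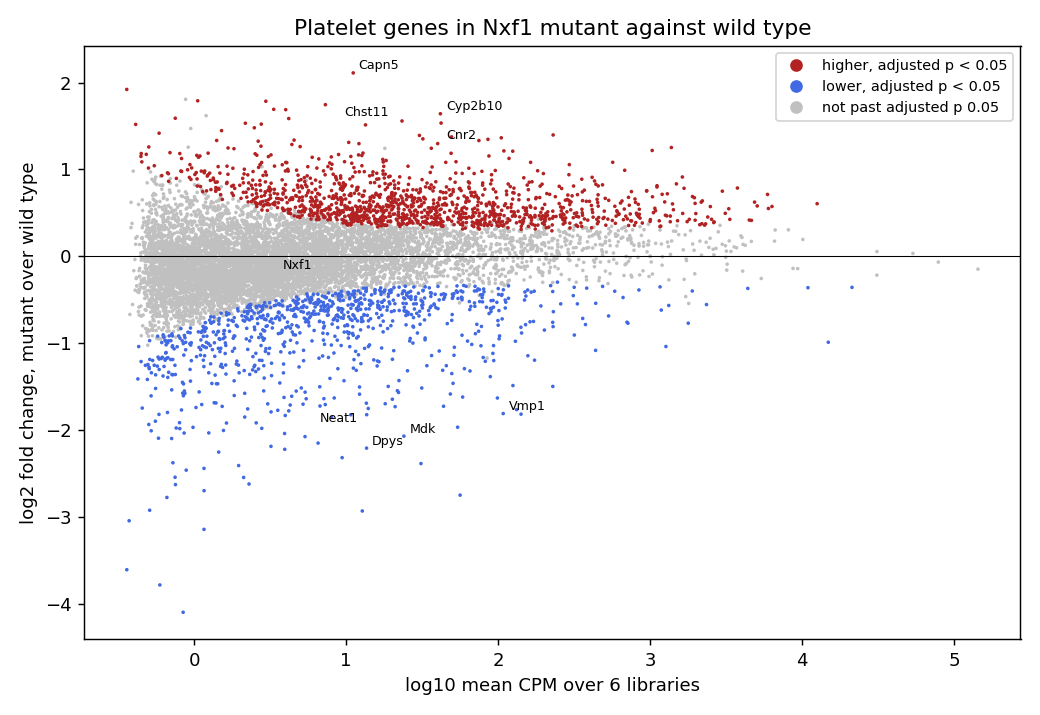
Log2 fold change, mutant over wild type (vertical axis), against log10 mean CPM over 6 libraries (horizontal axis), with 1 point per gene. Red points are the 1266 genes higher and blue points the 900 genes lower in the mutant, and Nxf1 at -0.19 lies among the grey genes that did not pass.

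Among named genes with a mean of at least 10 CPM, the calpain protease gene Capn5 (Entrez 12337, chromosome 7, 98121559 to 98178946) had the largest rise, from 4.17 ± 0.758 to 18.1 ± 2.89 CPM (SD, n = 3 each). Its log2 fold change was 2.11 ± 0.16 (SE, adjusted p = 2.95e-08 by edgeR). Cyp2b10, a cytochrome P450, rose by 1.64 on the log2 scale, Cnr2, the type 2 cannabinoid receptor, by 1.53, and Pdk1, an inhibitory kinase of pyruvate dehydrogenase, by 1.36. The remaining 8 of the 12 largest rises lay between 1.33 in Cdkn2d, a cyclin-dependent kinase inhibitor, and 1.56 in Chst11, and included Nlk (1.40) and the antiviral adaptor Mavs (1.39). Ufsp1 (1.51) and Ache, the acetylcholinesterase gene (1.35), are neighbours on chromosome 5, where Ache ends at 137294466 and Ufsp1 begins at 137294669.

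Among named genes of the same minimum level, Dpys, which encodes dihydropyrimidinase (Entrez 64705, chromosome 15, 39768485 to 39857470), had the largest fall, from 22.4 ± 4.31 to 4.84 ± 0.168 CPM (SD, n = 3 each). Its log2 fold change was -2.21 ± 0.15 (SE, adjusted p = 1.1e-08 by edgeR), and its neighbour Dcstamp had -1.59. The growth factor gene Mdk fell by 2.07 on the log2 scale, and Vmp1, an autophagy gene whose span also holds Mir21a, had -1.81. The nuclear noncoding RNA Neat1, which lies within 10 Mb of Nxf1 on chromosome 19, had -1.82. Log2 fold changes of Mras, Trafd1, Snx30, Nlrp6, Jcad and Atxn7l3b lay between -1.73 and -1.55. The value of Hk1os (-1.69) is uncertain, because it overlaps Hk1 and the library kit named in the labels does not mark strand. For the same reason the values given here for Vmp1, Vcl, Cnot7, Eif4a2, Hnrnpu, Ddit3, Ifit1, Tbxas1, Sptb, Plvap and Gadd45a are uncertain, since each overlaps another tested gene. All 24 genes of this group were called in every alternative run for named genes, which leaves out the stricter thresholds.

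**Figure D2:**
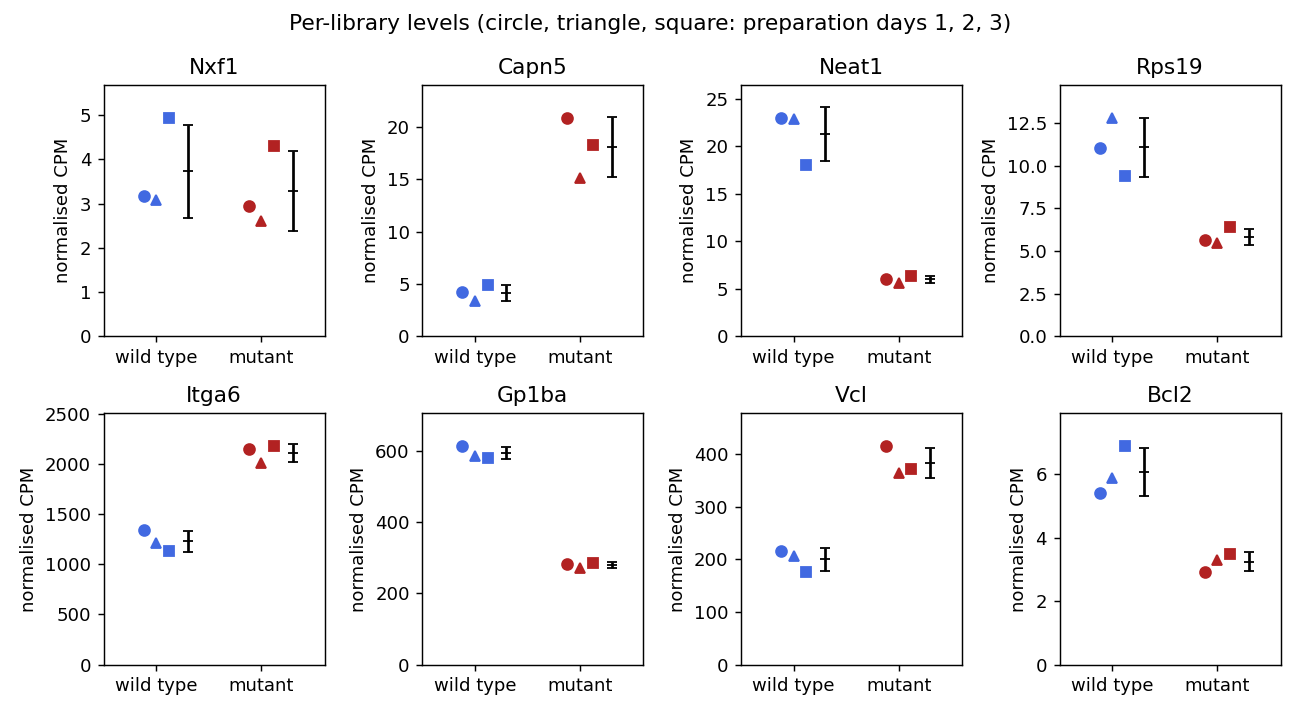
Normalised CPM (vertical axes from 0) of 8 genes in wild-type (blue) and mutant (red) libraries, with a circle, triangle and square for preparation days 1, 2 and 3 and bars for mean ± SD of 3 libraries. Nxf1 libraries overlap between genotypes, while Capn5, Itga6 and Vcl are higher and Neat1, Rps19, Gp1ba and Bcl2 lower in all 3 mutant libraries.

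Transcripts of cytosolic ribosomal proteins were lower as a group. Of 73 members 53 fell, 0 rose and 20 did not pass, and adjusted over the list alone 60 fell. Rps19 fell from 11.1 ± 1.72 to 5.83 ± 0.484 CPM (SD, n = 3 each), and Rpl36al and Rpl14 had log2 fold changes of -0.89 and -0.72. The medians within days 1, 2 and 3 were -0.49, -0.56 and -0.77. Camera with a preset correlation gave adjusted p = 1.27e-20, and adjusted p = 0.563 with an estimated correlation. These genes have many pseudogenes, and the list held only 0.118% of mutant and 0.181% of wild-type counts, so levels of single members are uncertain.

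Translation factors included 11 lower and 4 higher of 48 (23 and 4 with the day as a block, 14 and 4 adjusted over the list alone). Eif4g3 had a log2 fold change of -0.96, Eif4ebp1, a repressor of cap-dependent initiation, -0.76, and the helicase gene Eif4a2 0.72. Camera gave adjusted p = 0.000685, and adjusted p = 0.563 with an estimated correlation. Of 87 splicing factors 11 fell and 1 rose (32 and 5 with the block, 5 and 0 adjusted over the list alone), among them Prpf3 (-1.06), Snrnp200 (-0.59) and Tra2b (-0.49). Their list had adjusted p = 0.000402, and adjusted p = 0.563 with an estimated correlation. Of 23 heterogeneous nuclear ribonucleoproteins 8 fell and 0 rose (13 and 0 with the block, 11 and 0 adjusted over the list alone), including Hnrnpa3 (-0.82) and Hnrnpu (-0.44), with adjusted p = 0.0014, and adjusted p = 0.589 with an estimated correlation. Calls lost among 9 edgeR fits that each left out 1 library or day, with the highest adjusted p, were Prpf3 in 1 (0.0772), Tra2b in 1 (0.0859) and Hnrnpu in 2 (0.087). List medians were -0.23 for translation factors, -0.22 for splicing factors and -0.32 for the ribonucleoproteins, beside -0.33 for B cell markers. Loss of leukocyte RNA was not tested for these lists.

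RNA decay genes included 3 lower and 1 higher of 62 (12 and 3 with the block, 2 and 1 adjusted over the list alone). Zfp36l2, which destabilises AU-rich mRNA, fell from 61.6 ± 7.38 to 24.8 ± 2.15 CPM, Btg1 had a log2 fold change of -0.60, and the deadenylase gene Cnot7 had 0.59. The list had adjusted p = 0.0436 by camera, 0.0766 with the block and adjusted p = 0.773 with an estimated correlation, within a range of 0.0177 to 0.773 over its alternatives. Its adjusted p was 0.104, 0.0935 and 0.223 without mutant replicate 1, mutant replicate 2 or wild-type replicate 3, and 0.0621, 0.053 and 0.0722 without days 1, 2 and 3. Of 42 mRNA export genes Ncbp2, of the nuclear cap-binding complex (-0.97), and Srsf1 (-0.40) were lower and Gle1 (0.46) was higher (8 and 5 with the block, 1 and 0 adjusted over the list alone). That list did not pass (adjusted p = 0.114 by camera, 0.0408 on ranks, range 0.0408 to 0.589). Of 25 nuclear pore genes Pom121 (-1.37) was called, 4 were lower with the block, 1 was lower adjusted over the list alone, and the list had adjusted p = 0.367. Among the same 9 edgeR fits calls were lost, with the highest adjusted p in brackets, for Cnot7 in 1 (0.0663), Gle1 in 6 (0.24), Srsf1 in 6 (0.15) and Pom121 in 3 (0.152).

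Platelet cytoskeleton genes were higher. Of 55 members 30 rose and 1 fell, and 32 rose adjusted over the list alone. Vcl, which encodes vinculin, rose from 200.1 ± 21.1 to 383.8 ± 27.97 CPM (SD, n = 3 each), and Flna, which encodes filamin A (0.83), Lims1 (0.83) and the myosin heavy chain gene Myh9 (0.72) also rose. Camera gave adjusted p = 2.3e-10, and adjusted p = 0.589 with an estimated correlation. Of 38 adhesion and signalling receptor genes 15 rose and 3 fell (26 and 4 with the block, 21 and 3 adjusted over the list alone). Itga6 (0.78) and the fibrinogen receptor subunit Itgb3 (0.67) rose, while Gp1ba, a subunit of the von Willebrand factor receptor, fell from 594.2 ± 17.6 to 280.4 ± 8.12 CPM. That list had adjusted p = 0.000168, 0.172 among genes with a mean CPM of at least 10 (range 0.000104 to 0.773), and adjusted p = 0.773 with an estimated correlation. Of 35 granule cargo genes 14 rose and 2 fell (20 and 4 with the block, 16 and 3 adjusted over the list alone), including Pdgfa (0.82), Tgfb1 (0.78) and Vwf (0.75). Camera gave adjusted p = 0.00023, and adjusted p = 0.612 with an estimated correlation.

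In the same libraries the 10 most abundant genes took 37.9 ± 0.917% of counts in mutant and 43.2 ± 1.801% in wild-type platelets (SD, n = 3 each). This share was lower in the mutant on all 3 days, with p = 0.1 by a two-sided exact permutation test, the smallest 3 against 3 allows, and adjusted p = 0.229 over 16 measures. The medians of the ribosomal protein, translation, splicing, cytoskeleton, receptor and granule lists kept their sign under all 4 scalings of the libraries.

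**Figure D3:**
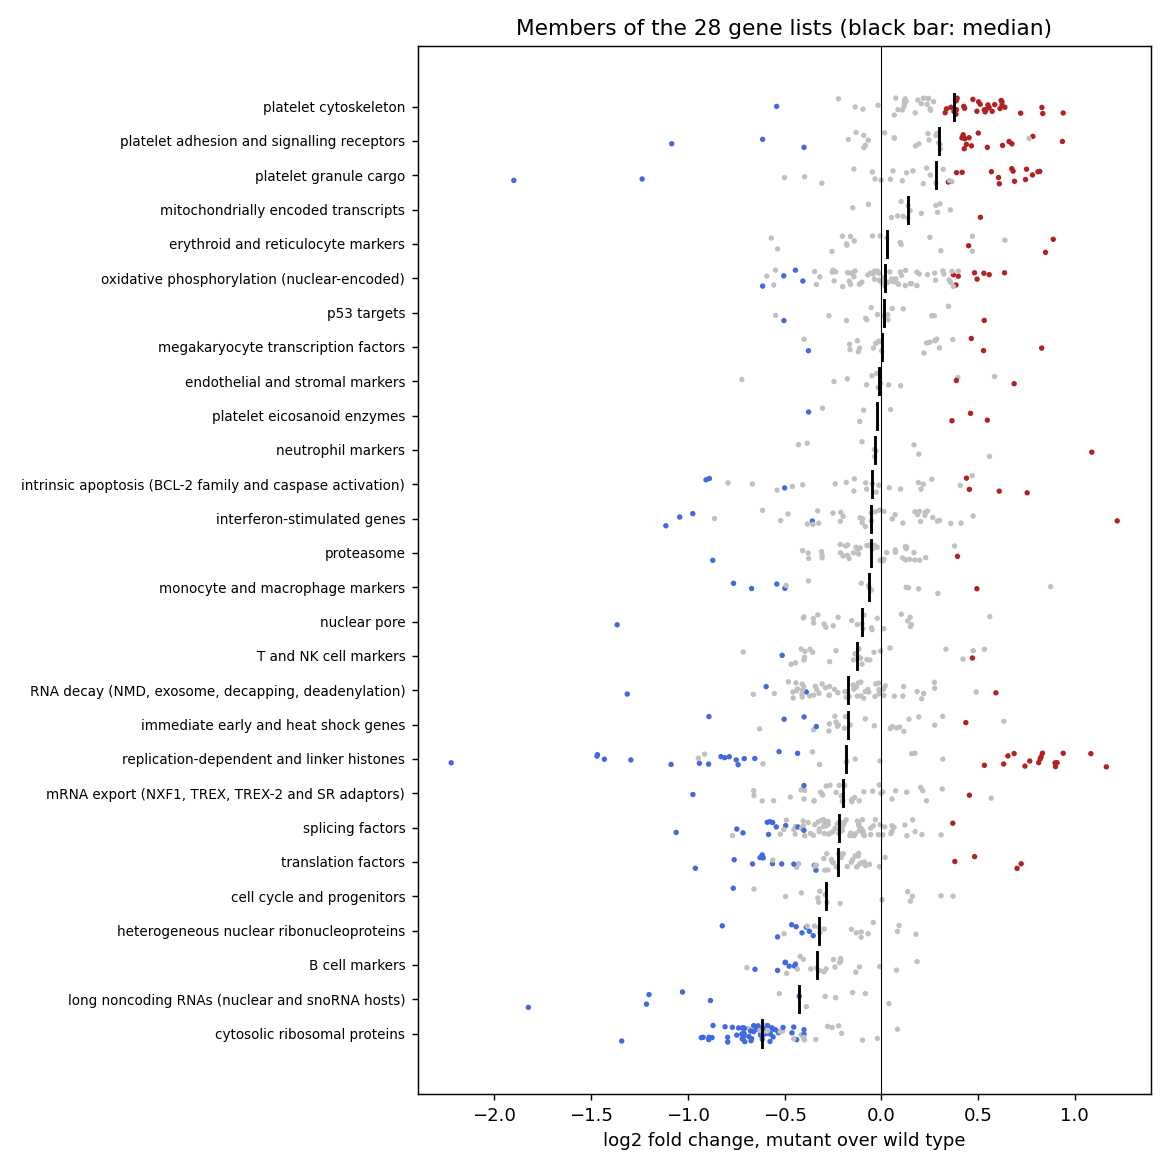
Log2 fold change, mutant over wild type (horizontal axis), of each measured member of the 28 gene lists (vertical axis, 1 line of points per list), with a black bar at the median. Red and blue points passed as higher or lower and grey points did not, and platelet cytoskeleton genes have the highest median (0.38).

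Long noncoding RNAs fixed as a list were lower, with 6 of 13 falling and 0 rising (7 and 0 adjusted over the list alone). Neat1 fell from 21.3 ± 2.85 to 6.01 ± 0.340 CPM and Norad from 130.3 ± 20.5 to 56.7 ± 4.43 CPM (SD, n = 3 each), and Tug1 (-1.21) and Snhg8 (-1.03) also fell. Camera gave adjusted p = 0.000168, and adjusted p = 0.589 with an estimated correlation. Histone genes moved in both directions. Of 45 members 16 rose and 17 fell (16 and 21 adjusted over the list alone), and the list did not pass (adjusted p = 0.333). All 3 H1 genes and 11 of 16 H2B genes rose, while 6 of 12 H2A and 7 of 9 H4 genes fell. Against their class, H2bc18 (-0.53) and H2bc21 (-1.47) were lower and H2ac12 (0.91) was higher, named after their values were seen, and of 5 H3 genes 1 rose and 2 fell. H3c14 (-2.22), H2ac6 (-1.43), H4c1 (-1.29) and H4c3 (-1.09) were lower. Copies of a histone class are nearly identical in sequence, so values of single copies are uncertain, and their joint share of counts was 0.443 ± 0.0188% in mutant and 0.372 ± 0.00145% in wild-type libraries (SD, n = 3 each, exact permutation p = 0.1).

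**Figure D4:**
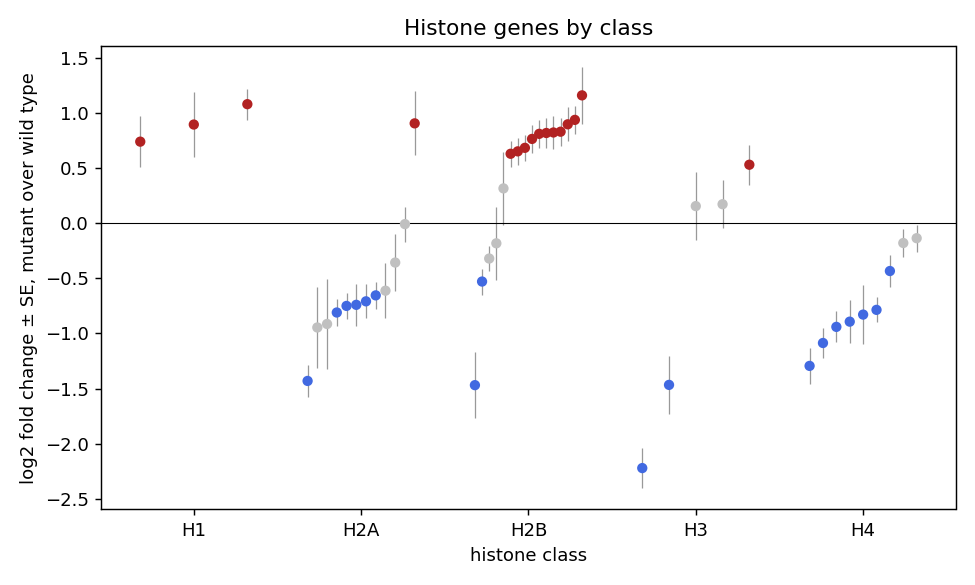
Log2 fold change ± SE, mutant over wild type (vertical axis), of each measured histone gene by class (horizontal axis), ordered by value within a class. Red and blue points passed as higher or lower and grey points did not, with 11 H2B genes above and 7 H4 genes below 0 among those that passed.

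Intrinsic apoptosis genes, which set platelet lifespan, moved in both directions, 4 higher and 3 lower of 29 (8 and 6 with the block, 4 and 3 adjusted over the list alone). Bcl2, a survival gene, fell from 6.05 ± 0.752 to 3.23 ± 0.296 CPM, the pro-apoptotic gene Bcl2l11 had a log2 fold change of -0.89, and the pore-forming effector Bak1 had 0.75. The list did not pass (adjusted p = 0.989). Of 42 interferon-stimulated genes the GTPase gene Igtp rose from 619.2 ± 54.5 to 1441 ± 56.4 CPM, while 4 fell, among them Samd9l (-1.11) and Ifit1 (-0.97). With the block 6 were higher and 7 lower, adjusted over the list alone 1 and 4, and the list had adjusted p = 0.525. Of 28 immediate early and heat shock genes Ddit3 (-0.89) and Hspa8 (-0.40) were among 4 lower and Hsp90aa1 (0.44) was higher (6 and 2 with the block, 4 and 1 adjusted over the list alone, adjusted p = 0.333). Of 17 p53 targets Mdm2 (0.53) was higher and Gadd45a (-0.50) lower (1 and 2 with the block, 1 and 1 adjusted over the list alone, adjusted p = 0.989). Of 42 proteasome genes Psmd13 (0.39) was higher and Psmb3 (-0.87) lower (3 and 5 with the block, 0 and 0 adjusted over the list alone, adjusted p = 0.525), and of 16 cell cycle genes Tpx2 (-0.77) was lower (4 with the block, 0 adjusted over the list alone, adjusted p = 0.333). In 9 edgeR fits with 1 library or day left out, calls were lost, with the highest adjusted p in brackets, for Hspa8 in 5 (0.182), Hsp90aa1 in 5 (0.322), Mdm2 in 1 (0.0859), Gadd45a in 2 (0.0949), Psmd13 in 6 (0.207), Psmb3 in 4 (0.122) and Tpx2 in 7 (0.212).

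After a length and GC correction Atp5e, named below, had a log2 fold change of -0.25 and was not called (adjusted p = 0.231 by edgeR). Of 69 nuclear-encoded oxidative phosphorylation genes 8 were higher, including Ndufb7 (0.64) and Ndufb9 (0.56), and 4 lower, including Atp5e (-0.50). With the block 20 were higher and 10 lower, adjusted over the list alone 6 and 4, and the list had adjusted p = 0.517, 0.00743 after a length and GC correction, with a range of 0.00743 to 0.951. Among 15 mitochondrially encoded transcripts ATP8, which overlaps ATP6 and is therefore uncertain, was called (0.51), as 1 adjusted over the list alone, 5 were higher with the block, and 3 were higher and 1 lower with library size alone. That list had a median of 0.14 and adjusted p = 0.0778, with a range of 1.6e-06 to 0.913, and passed without wild-type replicate 2 (0.00165), without day 2 (0.00298), without the 10 most abundant genes (0.0463), on ranks (0.0234) and after the length and GC correction (7.82e-05). Its share of counts was nevertheless 23.2 ± 0.398% in mutant and 25.9 ± 1.56% in wild-type libraries (SD, n = 3 each, exact permutation p = 0.1). Most of that share was held by mt-Rnr2, at 135657 and 150292 CPM, and mt-Rnr1, at 76656 and 80263 CPM. Megakaryocyte transcription factor genes included Zfpm1 (0.83), Mafg (0.53) and Ikzf5 (0.46) higher and Gfi1b (-0.38) lower of 23 (11 and 2 with the block, 3 and 1 adjusted over the list alone, adjusted p = 0.322). Of 8 eicosanoid enzymes Alox12 (0.55), Tbxas1 (0.46) and Ptgs1 (0.37) were higher and Pla2g4a (-0.38) lower, with the same counts adjusted over the list alone (adjusted p = 0.438). Leaving out 1 library or day in each of 9 edgeR fits ended calls, with the highest adjusted p in brackets, for Ndufb9 in 1 (0.0776), Atp5e in 3 (0.0875), ATP8 in 2 (0.11), Mafg in 3 (0.12), Ikzf5 in 6 (0.232), Gfi1b in 4 (0.191), Alox12 in 2 (0.0921), Tbxas1 in 5 (0.18), Ptgs1 in 7 (0.265) and Pla2g4a in 7 (0.259).

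Of 27 B cell markers 7 fell and 0 rose (17 and 1 with the block, 7 and 0 adjusted over the list alone, 2 and 0 with library size alone). H2-Aa fell from 91.3 ± 14.2 to 65.7 ± 5.95 CPM (SD, n = 3 each), and Cd79a (-0.54) and Igkc (-0.50) also fell. With library size alone H2-Aa (adjusted p = 0.0682 by edgeR) and Cd79a (0.0616) did not pass, nor did H2-Aa without mutant replicate 1 (0.0513), Cd79a without wild-type replicate 3 (log2 fold change -0.34, adjusted p = 0.0606), or H2-Aa (0.0607) and Igkc (0.39) after the length and GC correction. The lowest adjusted p over the alternatives was 7.91e-11 for H2-Aa, 5.81e-09 for Cd79a and 1.06e-09 for Igkc. The list had adjusted p = 0.0014, 0.144 without wild-type replicate 3 (range 0.000109 to 0.773), and adjusted p = 0.773 with an estimated correlation. Its share of counts was lower in the mutant on all 3 days, 0.0565 ± 0.00906% against 0.0719 ± 0.0193% (exact permutation p = 0.3). Monocyte and macrophage markers held 0.193 ± 0.0223% and 0.147 ± 0.0113% of counts, higher in the mutant on all 3 days (exact permutation p = 0.1). Lyz2, at 1913 and 1358 CPM, made up nearly all of that share, and the list median was -0.06. Of 16 members Lyz2 was higher (0.49) and 4 were lower, among them Fcgr1 (-0.67), Hmox1 (-0.50) and Ly6c2 (-0.76), with 1 and 4 adjusted over the list alone, 1 and 2 with library size alone, and adjusted p = 0.349. Of 28 T and NK cell markers Lat, which platelets also express, was higher (0.47) and Skap1 lower (-0.51), with 2 and 6 under the block, 0 adjusted over the list alone, and adjusted p = 0.333. Their share was 0.0267 ± 0.00150% in mutant and 0.0236 ± 0.00139% in wild-type libraries, most of it Lat at 202.9 and 146.4 CPM. Of 10 neutrophil markers Prtn3 (1.09) was called, with 0 adjusted over the list alone (2 higher and 2 lower with the block, adjusted p = 0.838). Of 14 endothelial and stromal markers Tie1 (0.69) and Plvap (0.39) were called, as 2 adjusted over the list alone (4 higher and 1 lower with the block, adjusted p = 0.384). Their share was 0.0148 ± 0.000386% against 0.0111 ± 0.000697%. Both shares were higher in the mutant on all 3 days (n = 3 each, exact permutation p = 0.1, adjusted p = 0.229 over 16 measures). Calls other than those of B cell markers were lost in the 9 edgeR fits with 1 library or day left out, with the highest adjusted p in brackets, for Lat in 5 (0.204), Skap1 in 8 (0.223), Prtn3 in 8 (0.206), Lyz2 in 4 (0.146), Hmox1 in 4 (0.129), Ly6c2 in 8 (0.145) and Plvap in 6 (0.187).

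Erythroid markers followed the preparation day. They held 4.08% of counts in the mutant and 4.93% in the wild-type library of day 1, with exact 95% binomial intervals of 4.077% to 4.092% and 4.927% to 4.943% that cover counting error only, and 0.530% to 0.726% in the other 4 libraries. The group means were 1.76 ± 2.01% and 2.08 ± 2.48%, lower in the mutant on all 3 days (SD, n = 3 each, exact permutation p = 0.6). Of 21 members Epor, the erythropoietin receptor gene (0.89), Sptb (0.85) and Aqp1 (0.45) were higher and 0 lower (6 and 5 with the block, 3 and 0 adjusted over the list alone). Aqp1 had 0.29 without mutant replicate 2 (adjusted p = 0.254 by edgeR) and was also not called without wild-type replicate 1 (0.0898), day 1 (0.126) or day 2 (0.194). The list had adjusted p = 0.145 (range 0.000109 to 0.823) and passed without mutant replicate 2 (0.00224), mutant replicate 3 (0.0278) or wild-type replicate 1 (0.000109).

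By camera with a preset correlation, 10 of the 28 lists passed, 3 higher and 7 lower, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.563. By fry, which tests whether the genes of a list move on balance one way, the splicing (adjusted p = 0.0558), granule cargo (0.0558), receptor (0.0809), RNA decay (0.164) and B cell (0.321) lists did not pass. In simulated data with no change, at least 1 list passed in 7 of 40 data sets, so the preset-correlation test called more often than its threshold states. The simulated genes were independent, so this rate leaves out correlation between genes and may be too low for the data. Within lists of the data that correlation was estimated at up to 0.698, in the mitochondrially encoded list. The median, mean and test differed in sign for the apoptosis, p53, eicosanoid, neutrophil and endothelial lists, none of which passed. With library size alone Gle1, Ptgs1, Ikzf5, Skap1, Prtn3, Ly6c2, Tpx2 and Psmb3 lost their calls as well.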

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

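The length and GC correction and the blocked fit without replicate 1 were chosen after the data were seen. The 2166 calls (1266 higher, 900 lower) became 3929 with the replicate block (2164 and 1765), 4077 with the length and GC correction and the block (2271 and 1806), 1332 at adjusted p under 0.01 (767 and 565) and 1214 against a minimum fold of 1.2 (654 and 560). With a mean CPM of at least 10, 725 genes were higher, and with the block without replicate 1, 1417 were lower. Stricter thresholds and fewer tested genes call fewer by construction, and for the others the cause was not tested. Leaving out libraries or days gave 1005 to 2389 genes, 485 to 1387 higher and 520 to 1002 lower. The 10 lists became 0 with an estimated correlation and 5 by fry. By edgeR the block ended the call of the RNA decay list and of no other list or named gene, and added Fth1. By DESeq2 it ended the call of Psmb3 (adjusted p = 0.0526, range 0.00034 to 0.122), added Fth1 and mt-Rnr2 (0.0476), and left Skap1, Ly6c2 and Tpx2 uncalled, as DESeq2 did without it. Of 113 called named genes, 71 were called in every alternative that tested them, 42 were lost in at least 1 and 0 reversed. The stricter thresholds were not run for named genes, and filters left some of these genes out. Prtn3 was lost in 13, Ly6c2 in 12, and Skap1 and Pla2g4a in 11 each. Nxf1 log2 fold change ranged from -0.4327 to 0.0774 (the latter without wild-type replicate 3) and passed in no alternative.

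Values of abundant genes that had not passed changed sign. Ctla2a log2 fold change was -0.0103 with upper-quartile factors, -0.0418 with library size alone, -0.0083 with quality weights, -0.13 with a mean CPM of at least 10, -0.001 without erythroid genes and -0.019 in the block without replicate 1, and -0.0768 to 0.1152 with libraries left out. Nrgn log2 fold change was -0.0218 with library size alone, -0.11 with a mean CPM of at least 10, and -0.0327 to 0.1248 with libraries left out. mt-Rnr1 log2 fold change was 0.1054 with the length and GC correction, 0.1064 with the block added, and -0.1805 to 0.0141 with libraries left out. The difference in erythroid share of -0.316 percentage points ranged from -1.48 to 1.11 with libraries left out and was 0.00907 without haemoglobin genes. Without the block 0% of simulated 1.2-fold changes were recovered. Far fewer genes were changed in the simulation than were called in the data, which made its adjustment stricter. How far depth and spread limit small changes in the data was therefore not measured.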

Other observations

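Long noncoding RNAs as an annotation class were lower in mutant platelets, beyond the list fixed beforehand. Of 232 such genes 114 fell and 10 rose (edgeR, adjusted p under 0.05), with a median log2 fold change of -0.56, against 661 lower and 1218 higher of 9107 protein-coding genes. The 77 that overlap no other annotated gene on either strand had 38 lower and 5 higher, with a median of -0.55, and values of the other 155 (76 lower and 5 higher) are uncertain because the kit does not mark strand. Protein-coding genes with 1 exon, histones left out, had 34 lower and 9 higher of 137, and those with 4 or more exons 492 lower and 1104 higher of 8196. Of 7 microRNA genes, chosen after their values were seen, 6 were lower, among them Mir23a, Mir27a and Mir24-2, which lie next to each other on chromosome 8 and are not independent. Because polyA RNA was sequenced, counts at microRNA genes need not stand for mature microRNAs.

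Chosen after the result was seen were the tests on RNA from leukocytes, on 1-exon genes, on exon numbers of long noncoding RNAs and on summed histone counts, and the requirement, applied alike to each test that set 3 pairs against a bound, that the mean margin over 3 pairs exceed 2 SD. Without that requirement leukocyte RNA would also have been argued against for the long noncoding RNAs.

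All 10 splits of the 6 libraries into 3 and 3 were refitted, too few for a share under 0.05. For genes, 1 split, the real one, called as many as 2166, and the highest other called 0 by edgeR, with 56 to 732 genes at an unadjusted p under 0.05, 0 by limma-voom and at most 12 by DESeq2. For lists, 5 splits, the real one included, passed at least the real 10, and the highest other passed 16. Among the 4 splits that part all 3 days, the real one passed 10 lists and the others 0, 12 and 6 (9 against 0, 12 and 6 with the block). The number of lists passed does not set the genotypes apart from other groupings.

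Lower ribosomal protein transcripts were weighed against 3 technical explanations. In the blocked fit the median was -0.62 and -0.51 after the length and GC correction, against that trend as the whole cause. The 21 members with at least 80% of 50-base words in no other GENCODE gene had a median of -0.6239, and the 52 below that share -0.6228. Words were taken from each gene's longest annotated transcript, which can be longer than the counted exons. For Rps19 there were 2608 words against a counted length of 629. The cut therefore cannot decide on reads shared with annotated pseudogenes. B cell markers had a median of -0.3259, above the ribosomal proteins by 0.263 ± 0.0903 (SD, 3 pairs). By list medians this argues against lost leukocyte RNA as the whole cause, though platelets could express some markers. Called markers fell further in the blocked fit, Cd79a by -0.53, Igkc by -0.49 and H2-Aa by -0.47. Within days 1, 2 and 3 Cd79a had -0.36, -0.37 and -0.80, against ribosomal medians of -0.49, -0.56 and -0.77. The argument thus holds for the list medians and not for each marker. An effect of the genotype is a hypothesis. Reads shared with annotated pseudogenes stay open, and unannotated copies and the age of the platelets stay open and untested.

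For lower long noncoding RNAs, the 212 genes with values lay below protein-coding genes matched on length, GC and mean CPM by a median of -0.4506, against those properties as the cause. RNA from leukocytes cannot be told apart from the genotype here, because the B cell median of -0.3259 lay above theirs by 0.242 ± 0.189 (SD, 3 pairs), with a lowest margin of 0.04, and H2-Aa was the most abundant called B cell marker named, at 65.7 and 91.3 CPM, in suspensions with over 98% CD41-positive events. Protein-coding genes with 1 exon lay below matched genes with 4 or more exons by -0.1546 (-0.16 with histones included), lower in each of 3 pairs. That difference was smaller than that of the long noncoding RNAs. Of 40 histones with 1 exon 12 rose, all 3 H1 genes among them, and 17 fell. Their median difference from matched genes was -0.4139, from -0.43 to -0.11 over the pairs. Ufsp1, also of 1 exon, rose, while of 16 long noncoding RNAs with 1 exon 0 rose and 13 fell. Against matched protein-coding genes with 4 or more exons, long noncoding RNAs with 1 to 3 exons (112 genes, 66 lower and 4 higher) had a median of -0.82. Those with 4 or more in any annotated transcript (100 genes, 35 lower and 6 higher, Neat1 and Tug1 among them) had -0.2383, from -0.38 to -0.15 over the pairs. Transcripts of these genes with fewer exons were not told apart, so whether few exons are the whole cause stays open. This holds for Neat1 too, whose 4 exons are the most of any annotated transcript and need not be those of the RNA counted. A candidate explanation is that some transcripts with few introns depend more on full Nxf1 function, a hypothesis found and tested on the same data. The rises of 12 histones and of Ufsp1 go against it as a general rule, with limits. Copies within a histone class are nearly identical, so these are not 12 independent rises. Among them H1f2 (91.46% of words unique, log2 fold change 1.08) and H1f3 (97.75%, 0.74) depend least on shared reads. Ufsp1 lies next to Ache, which also rose (1.35), and whether reads of Ache entered its count was not tested. The medians of 1-exon genes, histones among them, lay lower.

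Histone classes moved apart. Summed over each class, H2B rose above H4 by 1.22 in log2. Reads shared within a class leave such sums in place if they were counted, but not necessarily if they were dropped. Their treatment is not given in the sources used here, so the sums cannot decide on shared reads as the cause. The H2B genes with the largest shares of 50-base words unique to them moved in both directions. H2bc21 (100%, 0.852 CPM) had -1.47, H2bc6 (82.13%) -0.32, which did not pass, and H2bc9 (81.17%) 0.83. H2bc4 (69.38%) had 0.81, and H4c3 (80.42%) had -1.09. After the length and GC correction the class medians differed by 1.504, from 1.546 before it, against that bias. Summed H3 counts had -0.67 while the median H3 gene had 0.16, and 1 copy, H3c14, went from 6.51 to 1.39 CPM with 0% of its 50-base words unique to it. An effect of the genotype is a hypothesis, and histone RNA from other cells may contribute and was not tested. The libraries were made from polyA RNA, so these values need not stand for histone RNA without a polyA tail. Whether the share of histone RNA with a tail differed was not tested.

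Linked variants around Nxf1 were considered for the gene calls. Within 10 Mb of Nxf1 19.9% of 181 genes were called, against 22.1% of the other 9641 (Fisher's exact p = 0.527), so no excess was found there. Neat1 (chromosome 19, 5824708 to 5845480) lies in that window. A lack of excess over the region cannot decide for a single gene, so a linked variant stays open for Neat1.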
